A study of Mus musculus with 5 samples.

How the data were processed

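Chromatin contacts around the Sonic hedgehog gene Shh were measured by capture Hi-C, in which ligated pairs of DNA fragments are enriched for a chosen stretch of the genome before sequencing. The samples were limb buds of E10.5 mouse embryos of 5 homozygous mutant genotypes, each with 1 library. Per the labels, intraTAD2, intraTAD3 and intraTAD2-i4CTCF embryos came from mating, and intraTAD2-2xBorCTCF and intraTAD2-1xBorCTCF embryos came from tetraploid aggregation, in which embryonic stem cells are joined with tetraploid host embryos. The last 3 genotypes are called i4CTCF, 2xBorCTCF and 1xBorCTCF here. A map of the whole series named wild type, which belongs to no sample, served as the comparison and is given as the authors' value, so that 1 column of values belongs to no sample. Per its name, that map was made by capture Hi-C of E10.5 limb buds. Its embryos and library were not described further in the sources used here, and the series type includes third-party reanalysis. Ratios of mutant maps to wild type can therefore also reflect the origin of the library. What was changed in each allele was not given in the sources used here either, so genotypes are referred to by name.

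Per the labels' protocols, tissue was fixed with formaldehyde, chromatin was cut with DpnII, and the religated DNA was sonicated, captured with SureSelect probes and sequenced as paired-end reads. The submitters' processing notes name Bowtie2 2.2.6 and the builds mm9 and mm10, without saying what each was used for. Per the file names, reads of mapping quality 30 or more were kept and the maps were balanced by the Knight-Ruiz method, which scales every bin to the same total. The deposited values are a balanced contact signal for each pair of 5 kb bins, made by the authors separately for each map. Duplicate removal, the caller of contacts and the probe design were not given in the sources used here. Coordinates are those of the files on chromosome 5. The build was checked against GRCm38 (mm10) gene positions. Shifting the genes by up to 500 kb in 201 steps, the contact of 3 gene pairs was highest at a shift of 0 kb, with a mean of 3.01 on the log2 scale of distance-normalised contact against at most 0.951 beyond 50 kb.

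Balanced values equal a whole number of contacts times a factor of each bin. These factors and the whole contacts were recovered from the values, with 100% of the recovered values whole within 0.01. In intraTAD3, 6 bin pairs were not recovered. Undefined values were listed for 36 pairs in wild type, 61 in intraTAD3, 9 in 2xBorCTCF and 106 in 1xBorCTCF. In simulated maps 100% of counts were recovered exactly. The captured region spans 27,480,001 to 30,270,000 (2790 kb) in 558 bins, and 10 bins with under 25% of the median number of partners in any map were left out of all maps. Recovered contacts numbered 1,646,616 in wild type, 2,942,790 in intraTAD2, 2,848,921 in intraTAD3, 1,256,568 in i4CTCF, 1,121,373 in 2xBorCTCF and 1,975,131 in 1xBorCTCF. Of 155,961 bin pairs, 79.8%, 88.1%, 85.6%, 73.6%, 72.0% and 83.1% were listed in these maps, undefined values included.

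Since the maps were balanced separately, every value was divided by the mean of all bin pairs at the same distance in its own map, giving a distance-normalised contact with an average of 1. Windows were compared as the log2 ratio of their mean contact in each map. With 1 library per genotype there was no test. The 95% intervals come from a weighted Poisson error of the recovered contacts and cover counting error only, not the spread between embryos. They replaced an exact binomial interval on summed contacts after the first values had been seen. In 200 simulated comparisons of Shh to Lmbr1 contact with wild type without a change, the interval held 0 in 193, against 188 for the first form. With a planted log2 change of 0.32 it held that change in 177 of 200, and the mean recovered value lay between 0.28 and 0.30. How often the intervals hold the true value was not simulated for other windows, including those with fewer contacts, or between mutant maps. Each ratio was also placed as a percentile among all windows of the same size and distance in the same 2 maps, as a description of these libraries. These windows overlap, so their number is not a number of independent comparisons. Shares of contacts come from balanced values. Their intervals are Clopper-Pearson intervals of the share of recovered contacts, shifted onto the balanced share. They state counting error around the balanced share and are not exact for it.

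The windows, gene lists, thresholds and most alternatives were fixed before the data were examined. The Shh window held the bins of Shh and 1 bin either side. Intron 5 of Lmbr1, which holds the ZRS limb enhancer of Shh, had been planned as its partner. Introns were not in the annotation used here, so the whole Lmbr1 gene was taken instead. For the other genes, the gene body and 1 bin either side replaced the planned transcription start. The Shh topologically associating domain (TAD) ran between the wild-type insulation minima nearest to Shh and to the far end of Lmbr1, with a prominence of at least 0.2 on the log2 scale. Insulation was the log2 of the mean contact between the 100 kb on either side of a bin over the mean of that quantity in the map. Contacts across the borders used flanks of 500 kb. Windows of the TAD, its parts and its flanks held bin pairs at least 50 kb apart, and other windows could also hold closer pairs. Changed bin pairs differed 2-fold or more after smoothing over 3 by 3 bins with a pseudocount of 0.1. The count was set beside the mean of 10 simulations in which both maps share 1 contact pattern and differ in counting noise alone. A planted block of 400 bin pairs raised 3-fold was called higher in 86.6% to 87.7% of its pairs and lower in 0%. The genes named were Shh, Lmbr1, the fixed lists of neighbours on the En2 side (Paxip1, Htr5a, Insig1, En2, Cnpy1, Rbm33), in the TAD (Shh, Rnf32, Lmbr1) and on the Mnx1 side (Nom1, Mnx1, Ube3c, Dnajb6), and genes in the anchors of the 3 regions of changed contact ranked first in each direction and comparison.

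Alternatives varied the scaling, the expected value, the comparison map, the windows, the bin size, the smoothing, the threshold and the pseudocount. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.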

Results

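Contact maps of the Shh locus were collected from E10.5 limb buds of 5 mutant genotypes and set against the authors' wild-type map. Shh encodes the secreted signal that patterns the limb along its thumb-to-little-finger axis, and its limb enhancer ZRS lies inside the neighbouring gene Lmbr1. The series addresses how the function of an enhancer depends on its position at this locus. Each genotype had 1 library, with 1,121,373 (2xBorCTCF) to 2,942,790 (intraTAD2) recovered contacts, and wild type had 1,646,616. The wild-type map belongs to no sample, so in every ratio to wild type the genotype cannot be told apart from the origin of the library. No spread between embryos could be estimated, so the 95% intervals below state counting error only.

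In the wild-type map Shh (chromosome 5, 28,456,840 to 28,467,101) and Lmbr1 (29,229,802 to 29,378,421) lay 762.7 kb apart, and a TAD of 905 kb held Shh and most of Lmbr1. Their contact was 5.73 times the average at that distance. The domain was bounded by an insulation minimum of -1.03 at 28,445,001, between Shh and Rbm33, and by one of -0.80 at 29,355,001, inside Lmbr1. Contacts inside the domain averaged 1.45, contacts with the flank on the side of En2 0.951, and contacts with the flank on the side of Mnx1 0.721.

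The first comparison asked how the contact of Shh with Lmbr1 differed between the mutant maps and wild type. It was higher in intraTAD2, at 6.17 (log2 ratio 0.11, interval 0.033 to 0.18), and in intraTAD3, at 6.56 (0.20, 0.12 to 0.27). In 1xBorCTCF it was lower, at 4.94 (-0.22, -0.30 to -0.14). The values of 6.00 in i4CTCF (0.066, -0.024 to 0.16) and 5.52 in 2xBorCTCF (-0.055, -0.15 to 0.043) did not differ from wild type beyond counting error. These windows held 1729 to 5977 contacts. The Lmbr1 window includes the stretch from 29,305,001 to 29,320,000, which had few contacts in intraTAD3. Its bins at 29,305,001 and 29,310,001 were left out of all maps. The bin at 29,315,001 was kept, with 0.0518 of the wild-type contacts in intraTAD3. The intraTAD3 value therefore describes mainly the rest of Lmbr1, and contact with the enhancer itself was not resolved. Among 373 windows of the same size and distance the 1xBorCTCF ratio stood at percentile 7.24 and the intraTAD3 ratio at percentile 90.3, so changes of this size also occurred elsewhere in the same maps.

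**Figure D1:**
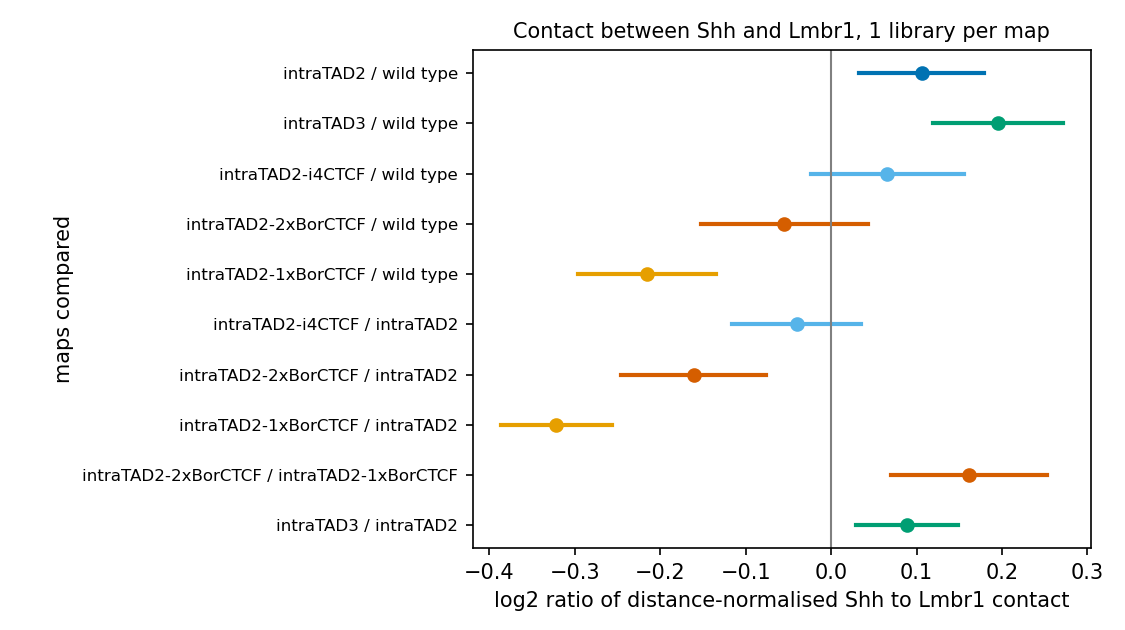
Each point is the log2 ratio of the distance-normalised contact of Shh with Lmbr1 between a pair of maps (1 library each), and each bar is its 95% counting interval. Against wild type, intraTAD2 (0.11) and intraTAD3 (0.20) lie above 0 and 1xBorCTCF (-0.22) below it, and against intraTAD2 the lowest value is that of 1xBorCTCF (-0.32).

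Contacts of Shh with Rnf32, a RING finger gene next to Lmbr1, followed the same order of maps. They were 3.70 in wild type, 4.35 in intraTAD2 (0.24, 0.11 to 0.36), 4.54 in intraTAD3 (0.29, 0.17 to 0.42) and 3.05 in 1xBorCTCF (-0.28, -0.42 to -0.14). In i4CTCF (4.11) and 2xBorCTCF (3.45) the intervals included 0. Of the 2 listed genes that share the TAD with Shh, both rose in intraTAD2 and intraTAD3, both fell in 1xBorCTCF, and neither changed in the other maps beyond counting error. The windows of Rnf32 and Lmbr1 are adjacent and share bins, so these are not 2 independent observations.

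On the En2 side, the contact of Shh with the homeobox gene En2 split the mutant maps. It was 1.80 in wild type and lower in intraTAD2 (1.36, log2 ratio -0.40, -0.58 to -0.22), intraTAD3 (1.48, -0.28, -0.47 to -0.092) and 2xBorCTCF (1.44, -0.32, -0.57 to -0.065). In i4CTCF it was higher at 2.24 (0.32, 0.11 to 0.53), as it was in 1xBorCTCF at 2.21 (0.30, 0.12 to 0.48). Among 496 windows of the same size and distance these En2 ratios stood at percentiles 3.83 in intraTAD2, 13.3 in intraTAD3, 9.68 in 2xBorCTCF, 91.9 in i4CTCF and 89.9 in 1xBorCTCF. Cnpy1, which neighbours En2, had a contact of 1.05 with Shh in wild type and was lower in intraTAD2 (-0.45, -0.59 to -0.31), intraTAD3 (-0.38, -0.52 to -0.23) and 2xBorCTCF (-0.35, -0.54 to -0.16). Paxip1, a gene of the DNA damage response and the listed gene farthest from Shh on this side, was higher in 2xBorCTCF (1.21 against 0.797, 0.60, 0.30 to 0.90) and 1xBorCTCF (1.06, 0.42, 0.17 to 0.67), and Insig1 was higher in 2xBorCTCF (0.949 against 0.705, 0.43, 0.012 to 0.84). Of the 6 genes on this side, 0 rose and 2 fell in intraTAD2 and in intraTAD3, 1 rose in i4CTCF, 2 rose and 2 fell in 2xBorCTCF, and 2 rose in 1xBorCTCF. Rbm33, the gene next to Shh across the border, stayed at 0.488 to 0.536 in all 6 maps, and Htr5a at 0.730 to 0.866.

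On the Mnx1 side the contact of Shh with the homeobox gene Mnx1 was 5.18 in wild type, lower in 2xBorCTCF at 3.04 (-0.77, -1.08 to -0.46), and lower in intraTAD2 at 4.29 (-0.27, -0.48 to -0.064) and intraTAD3 at 4.23 (-0.30, -0.51 to -0.077). Among 352 windows these ratios stood at percentiles 4.83, 20.2 and 19.9, so falls as large as those in intraTAD2 and intraTAD3 were common in the same maps. For the other 3 genes of this side, Nom1, Ube3c and Dnajb6, the intervals of the ratio to wild type included 0 in all 5 mutant maps. From the viewpoint of Lmbr1, the contact with Rbm33 was higher in intraTAD2 (2.94 against 2.64, 0.16, 0.11 to 0.21), intraTAD3 (0.19, 0.13 to 0.24) and i4CTCF (0.083, 0.018 to 0.15) and lower in 1xBorCTCF (2.47, -0.096, -0.15 to -0.039). Lmbr1 had less contact with Ube3c in 4 of the 5 mutant maps, with log2 ratios of -0.10 to -0.086 (0.853 in wild type, 0.798 in intraTAD2), and with Mnx1 in i4CTCF (0.414 against 0.492, -0.25, -0.42 to -0.077). Its contact with Htr5a, 1.27 in wild type, was higher in intraTAD2 (0.20, 0.022 to 0.37), intraTAD3 (0.22, 0.028 to 0.41), i4CTCF (0.25, 0.027 to 0.47) and 2xBorCTCF (0.35, 0.14 to 0.57), and that with Paxip1, 1.38 in wild type, in intraTAD2 (0.17, 0.039 to 0.30), intraTAD3 (0.14, 0.0071 to 0.28) and 1xBorCTCF (0.18, 0.040 to 0.31).

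**Figure D2:**
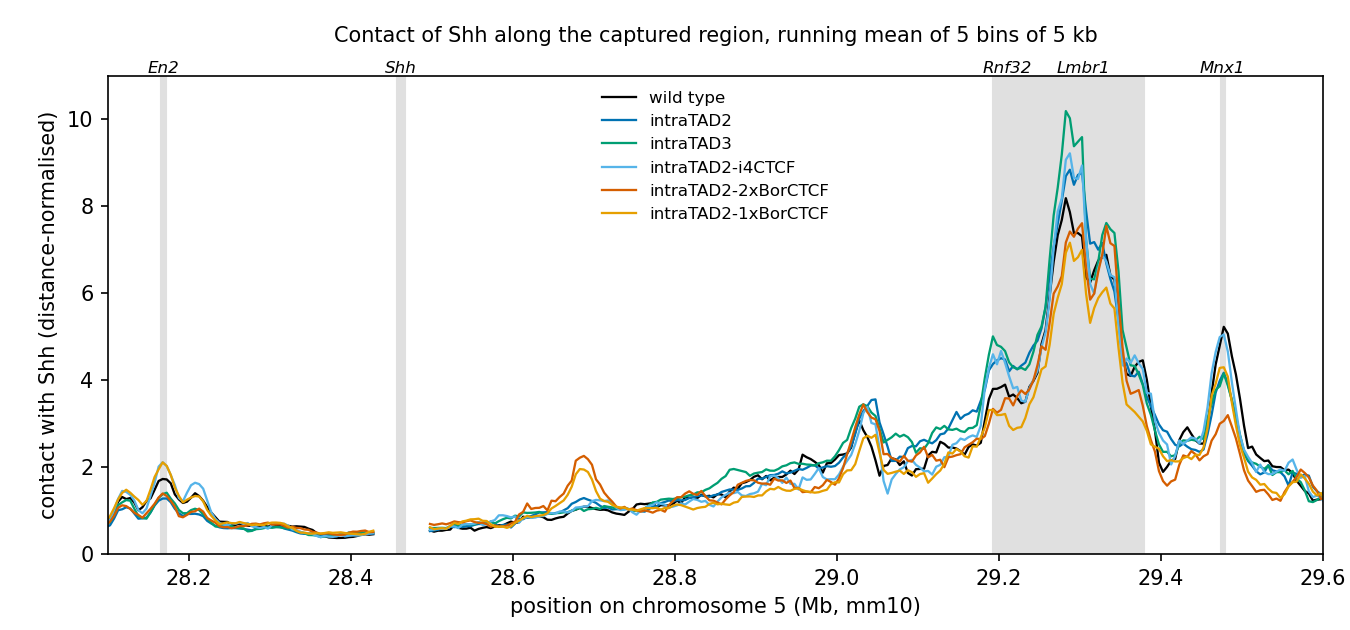
Lines give the distance-normalised contact of Shh along chromosome 5 (running mean of 5 bins of 5 kb) in the 6 maps, with En2, Shh, Rnf32, Lmbr1 and Mnx1 shaded. All maps peak over Lmbr1, where the window means run from 4.94 in 1xBorCTCF to 6.56 in intraTAD3.

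Looking at the whole domain, contacts inside the Shh TAD moved little. Against the wild-type average of 1.45, intraTAD2 differed by 0.052 on the log2 scale (0.039 to 0.065). The average was 1.53 in intraTAD3 (0.077, 0.063 to 0.090), 1.49 in i4CTCF (0.041, 0.025 to 0.058), 1.42 in 2xBorCTCF (-0.026, -0.043 to -0.0090) and 1.38 in 1xBorCTCF (-0.069, -0.083 to -0.054). None of 378 windows of the same size had a lower ratio in 1xBorCTCF than the TAD. These windows of 905 kb overlap heavily in a region of 2790 kb, so few of them are independent. Values were also scaled by the map total and set against all bin pairs at the same distances. The ratios were then 0.021 in intraTAD2, 0.045 in intraTAD3, -0.0050 in 2xBorCTCF and -0.031 in 1xBorCTCF. Such scaling largely repeats the main normalisation with a different weighting of bin pairs, so it is no independent check. Contacts across the border on the En2 side ranged from 0.971 to 1.01 in the mutant maps and those across the border on the Mnx1 side from 0.671 to 0.699. On the En2 side the difference from wild type turned negative in intraTAD2 (-0.018) and came to 0.000018 in intraTAD3 with that scaling. Compared with the median of the other 5 maps, the direction turned in intraTAD2 and intraTAD3 at both borders.

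Insulation at the border between Shh and Rbm33 was weaker in both BorCTCF maps, the 2 from tetraploid aggregation. It was -0.82 in 2xBorCTCF (0.21 above wild type, 0.062 to 0.35, percentile 91.0 among all bins) and -0.90 in 1xBorCTCF (0.13 above wild type, 0.031 to 0.23, percentile 92.1), against -1.07 in intraTAD2, -1.01 in intraTAD3 and -1.04 in i4CTCF, whose intervals included no difference from wild type. The border inside Lmbr1 had values of -0.86 to -0.77 in the 5 mutant maps, with every interval including the wild-type level of -0.80. Windows of 50 kb, however, put intraTAD3 at -0.098 relative to wild type. To the left of the border such a window begins at 29,305,001, in the stretch with few contacts in intraTAD3. A stronger border and the loss of contacts in that stretch can therefore not be told apart by this value.

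Of all contacts of Shh at 20 kb or more, 53.6% (52.9 to 54.2) fell in its TAD in wild type. That share was 58.9% (58.4 to 59.4) in intraTAD2, 59.2% (58.7 to 59.7) in intraTAD3 and 57.3% (56.5 to 58.1) in 2xBorCTCF. It was 54.3% (53.5 to 55.1) in i4CTCF and 53.1% (52.5 to 53.7) in 1xBorCTCF. The share on the Mnx1 side was 17.0% in wild type and 13.8% to 15.8% in the mutant maps. On the En2 side it was 29.1% in wild type, lower in intraTAD2 (26.8%) and intraTAD3 (26.6%), and higher in 1xBorCTCF (31.7%, 31.2 to 32.2).

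The next comparison set the 3 genotypes whose names extend intraTAD2 against intraTAD2 itself. Shh to Lmbr1 contact was lower in 2xBorCTCF (-0.16, -0.25 to -0.076) and in 1xBorCTCF (-0.32, -0.39 to -0.26), at percentiles 18.0 and 5.63 of 373 windows. In i4CTCF it did not differ beyond counting error (-0.040, -0.12 to 0.035). Contact of Shh with En2 was higher in i4CTCF (0.72, 0.53 to 0.90) and 1xBorCTCF (0.70, 0.54 to 0.85), both at percentile 99.6 of 496 windows, and 1.44 against 1.36 in 2xBorCTCF, within counting error. Cnpy1 moved the same way in i4CTCF (0.57, 0.42 to 0.72) and 1xBorCTCF (0.39, 0.27 to 0.52), and Paxip1 was higher in all 3, most in 2xBorCTCF (0.74, 0.47 to 1.01). Rnf32 was lower in 2xBorCTCF (-0.34, -0.49 to -0.19) and 1xBorCTCF (-0.51, -0.63 to -0.39). Of the 6 genes on the En2 side, 3 rose in i4CTCF, 2 in 2xBorCTCF and 3 in 1xBorCTCF, and 0 fell. Contacts inside the TAD were lower in 2xBorCTCF (-0.078, -0.092 to -0.063) and 1xBorCTCF (-0.12, -0.13 to -0.11), and came to -0.026 and -0.052 with values scaled by the map total and set against all bin pairs at the same distances. The border next to Shh was less insulated in 2xBorCTCF (0.25, 0.12 to 0.38, but 0.065 with windows of 50 kb) and 1xBorCTCF (0.17, 0.091 to 0.25), and that of 2xBorCTCF inside Lmbr1 was more insulated (-0.079, -0.15 to -0.012). Both BorCTCF samples came from tetraploid aggregation and intraTAD2 from mating, so allele and embryo source cannot be told apart.

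Between the 2 BorCTCF maps, both made by tetraploid aggregation, Shh to Lmbr1 contact was higher in 2xBorCTCF (0.16, 0.070 to 0.25). Its contact with En2 was lower (-0.62, -0.85 to -0.38), as were those with Cnpy1 (-0.29, -0.47 to -0.11) and Mnx1 (-0.58, -0.88 to -0.29). Dnajb6, a chaperone gene, had more contact with Shh in 2xBorCTCF (1.04 against 0.790, 0.40, 0.050 to 0.75). Contacts inside the TAD were 0.043 higher on the log2 scale (0.027 to 0.058, and 0.026 with values scaled by the map total and set against all bin pairs at the same distances).

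Between the 2 other intraTAD genotypes, both from mating, intraTAD3 had slightly more Shh to Lmbr1 contact than intraTAD2 (0.089, 0.030 to 0.15). The limit given above for the Lmbr1 window in intraTAD3 applies here too. Of the 10 listed neighbours outside the TAD, 0 changed their contact with Shh between intraTAD2 and intraTAD3 beyond counting error.

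Across the region, 9144 of 145,069 bin pairs differed 2-fold or more between intraTAD2 and wild type, 5330 of them higher. The totals were 9883 in intraTAD3, 15,241 in i4CTCF, 17,075 in 2xBorCTCF and 11,127 in 1xBorCTCF. Counting noise alone gave 9138, 9733, 14,811, 16,061 and 10,868 changed pairs in these comparisons. Against intraTAD2 the totals were 11,749 in i4CTCF, 13,836 in 2xBorCTCF, 7490 in 1xBorCTCF and 6215 in intraTAD3. Between 2xBorCTCF and 1xBorCTCF 14,814 pairs changed. The ratio of observed to simulated totals lay between 0.989 and 1.06 in all 10 comparisons, so counting noise alone gave nearly as many changed pairs as were observed. The totals still exceeded it by 4.35 SD over the simulations in 2xBorCTCF (SD 233) and 3.07 SD in i4CTCF (SD 140) against wild type. In 2xBorCTCF against intraTAD2 the excess was 2.73 SD. The SDs here and below cover the spread of 10 simulations from a pattern built out of the maps compared. An error in that pattern is not part of them, so these excesses were not firmly told apart from counting noise. Among pairs within 500 kb, a limit added after the data were seen, intraTAD2 had 227 changed pairs against 230 simulated, intraTAD3 271 against 249, i4CTCF 541 against 503, 2xBorCTCF 762 against 602 (SD 30.2) and 1xBorCTCF 403 against 313 (SD 19.9) relative to wild type. In the 5 comparisons between mutant maps the ratio of observed to simulated was 1.07 to 1.20 within that limit.

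The regions of changed contact ranked first in each direction joined stretches 2080 kb to 2705 kb apart (median over their bin pairs) and held 1 to 46 contacts, against 1 to 67 in the comparison map. The sizes of such regions under counting noise alone were not simulated. The regions below are therefore a description and were not told apart from counting noise. In intraTAD2 the first of them rose between Dpp6 with Speer4b and Dnajb6 (46 contacts against 8 in wild type, 1.25 against 0.212), and the first that was lower joined Dpp6 with Speer4b to Ube3c (10 contacts against 26, 0.237 against 1.76). In i4CTCF the first lower region joined Dpp6 to Garem2, Hadha, Hadhb and Adgrf3 (7 contacts against 57), and in 2xBorCTCF Dpp6 with Speer4b to Tyms, Garem2 and Hadha (4 contacts against 34). Il6, Selenoi, Paxip1, Nom1 and Mnx1 lay in other anchors. One region touched Shh itself, a gain in intraTAD3 over intraTAD2 with Dpp6 and Speer4b (14 contacts against 2, 0.845 against 0.0456).

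The similarity of the maps, as Spearman correlation over 83,228 bin pairs 50 kb to 1000 kb apart, was highest between intraTAD2 and intraTAD3 (0.879). These 2 maps held the most recovered contacts. Wild type had correlations of 0.736 to 0.827 with the mutant maps (median 0.781), and the mutant maps had a median of 0.802 with each other. In 7 pairs of mutant maps the correlation lay below the highest one with wild type. The correlations with wild type followed the order of recovered contacts, from intraTAD2 (0.827) and intraTAD3 (0.814) through 1xBorCTCF (0.781) and i4CTCF (0.768) to 2xBorCTCF (0.736). Depth and likeness of the maps can therefore not be told apart in these correlations. Contacts per bin correlated at 0.919 to 0.938 between wild type and the mutant maps but at 0.971 to 0.988 among the mutant maps, so that wild type stood apart from all 5 mutant maps in contacts per bin.

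A stretch nearly without contacts marked 1 genotype. In intraTAD3 the 15 kb from 29,305,001 to 29,320,000, inside Lmbr1, held 739 contacts, 2.55% of an average stretch of that length, against 80.9% to 115% in the other 5 maps. Contacts between the 20 kb on its left and the 20 kb on its right were 1.37 in intraTAD3 and 0.828 in wild type (0.73, 0.57 to 0.89). A bin at 29,180,001 was empty in all 5 mutant maps and held contacts in wild type. Bins at 29,055,001 and 30,225,001 were empty in wild type. The bin at 30,225,001 also had too few partners in 2xBorCTCF.

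**Figure D3:**
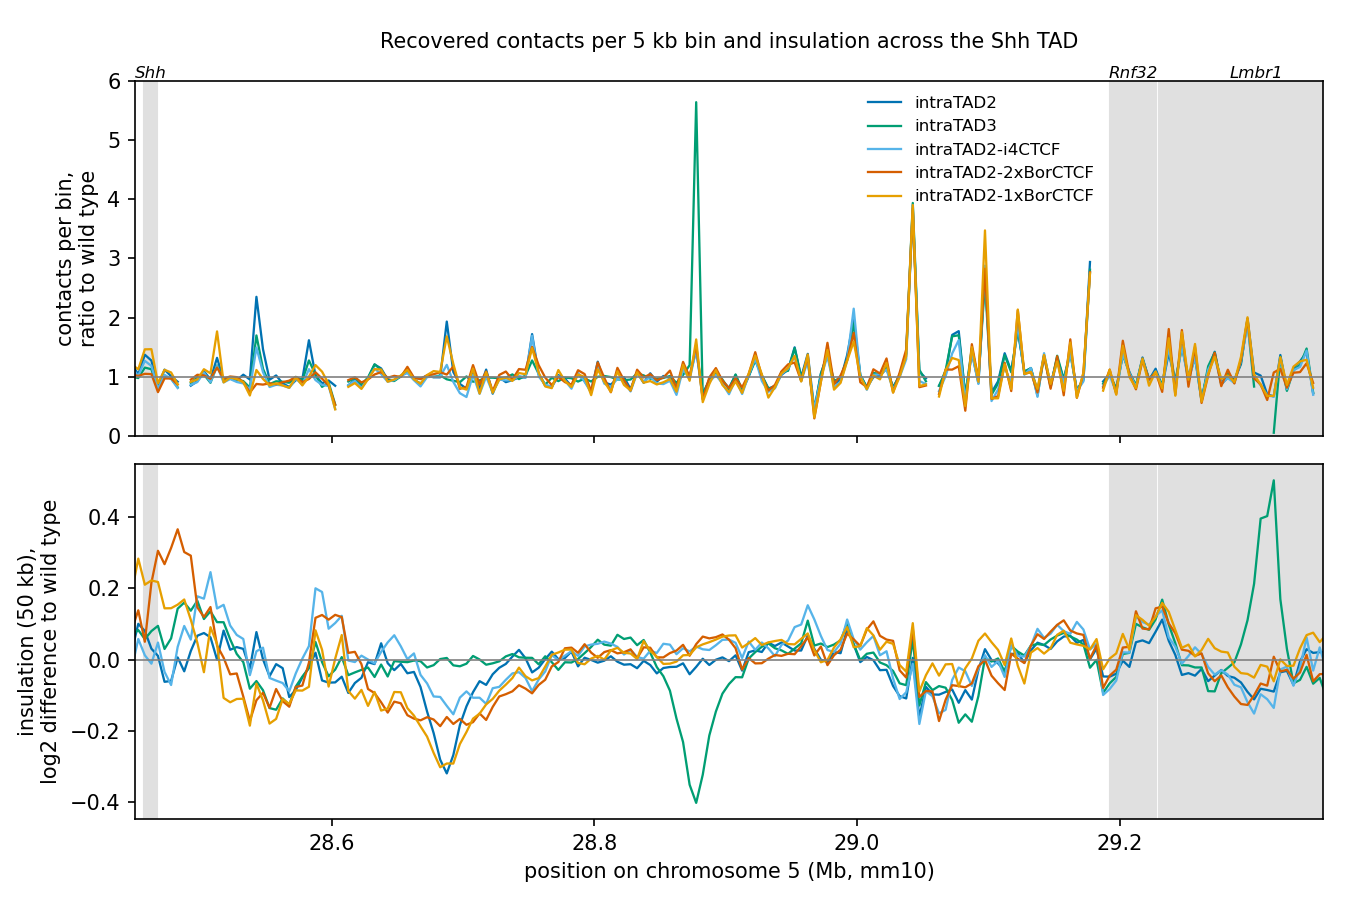
The upper panel shows the recovered contacts of each 5 kb bin of the Shh TAD, scaled by the map total, as the ratio to wild type, and the lower panel the log2 difference in insulation (50 kb windows) from wild type, for the 5 mutant maps. A bin at 28,685,001 stands at 1.93 in intraTAD2 and 1.68 in 1xBorCTCF, a bin at 28,875,001 at 5.64 in intraTAD3, and insulation falls at the same places.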

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

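All tests in this part were chosen after the pattern had been seen, except the share of odd counts in the raised bins. Its outcome was stated in advance, but the recovery of counts had largely fixed it. Bins were picked out because their contacts, scaled by the map total and compared with the median of the other maps, lay at least 5 robust SDs above the typical bin and above wild type, among the first 3 bins of each map and among bins with at least 0.1% of the contacts in the median of the other maps.

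A bin at 28,685,001 to 28,690,000, in the long noncoding RNA gene 9530036O11Rik and 217.9 kb from Shh, held more contacts than wild type in intraTAD2 (1.93-fold, 1.89 to 1.97) and in 1xBorCTCF (1.68-fold, 1.64 to 1.72), and a bin at 28,875,001 to 28,880,000, in no gene and 407.9 kb from Shh, held 5.64-fold the wild-type contacts in intraTAD3 (5.46 to 5.83). That second bin also stood at 1.44 to 1.63 times wild type in the other 4 mutant maps, and intraTAD3 at 3.86 times the median of the other 5 maps. The shares of odd counts were at least 50.3% in each raised bin. They cannot decide on a wrong factor in the recovery of counts. The recovery itself divided out any whole number common to all counts of a bin. A yield that drifts along the region is argued against by the neighbouring bins, whose ratios reached at most 1.21. Sequence added at these places in the alleles remains a candidate explanation. Insulation measured without the bin itself fell below wild type there by at least 4.08 SD over all bins (-4.08 in 1xBorCTCF as the weakest). This was found on the same maps. The fall concerns contacts across the bin and cannot show why the bin itself held more contacts. In i4CTCF and 2xBorCTCF, whose names also contain intraTAD2, the first bin stood at 1.20-fold and 1.04-fold and insulation differed by -1.66 and -1.68 SD.

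In intraTAD3, 15 kb of Lmbr1 from 29,305,001 to 29,320,000 lost nearly all contacts. Reads that cannot be mapped or captured there are argued against by the other maps, which held at least 80.9% of the contacts of an average stretch. A filter on this file alone is argued against by the contacts across the stretch, which exceeded every other map by at least 0.66 on the log2 scale. Missing sequence in the allele is a candidate explanation, since the rise of these contacts over wild type stood at percentile 99.8 of 546 windows of the same size.

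Shh had more contact with the bins beside 28,685,001 in both BorCTCF maps than in wild type (1.08), at 2.02 in 2xBorCTCF (log2 ratio 0.90, 0.67 to 1.13) and 1.78 in 1xBorCTCF (0.72, 0.52 to 0.92), with a smaller rise in intraTAD2, which came from mating (1.28, 0.24, 0.038 to 0.44). Balancing of a single bin with changed coverage is argued against, because the rise with the 4 neighbouring bins was also present in the contacts before balancing, at 0.85 in 2xBorCTCF (0.64 to 1.06) and 1.01 in 1xBorCTCF (0.82 to 1.19). Low depth is argued against by i4CTCF, of similar depth, where the ratio was -0.043. BorCTCF and the embryos from tetraploid aggregation cannot be told apart, since 0 maps separate them, so an effect of either stays open, though neither covers the smaller rise in intraTAD2. The allele itself is the biological explanation that the genotypes name, and it was not tested apart from the embryo source.

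Other bins met the same rule. The bin at 27,965,001 held 2.39-fold the wild-type contacts in intraTAD2, 2.21-fold in intraTAD3 and 2.39-fold in i4CTCF, against 1.30-fold in 2xBorCTCF and 1.39-fold in 1xBorCTCF. The bin at 27,975,001 stood at 1.71 in intraTAD2, 1.43 in intraTAD3 and 1.54 in i4CTCF, against 0.92 in 2xBorCTCF and 0.953 in 1xBorCTCF. The bin at 30,090,001 stood at 1.62 in i4CTCF, 1.53 in intraTAD2 and 1.47 in intraTAD3, against 0.991 in 2xBorCTCF and 1.13 in 1xBorCTCF. At these 3 bins the maps from mating lay above those from tetraploid aggregation. Each of the 3 bins was picked for being raised in a map from mating, so this difference is partly built into the choice. In 2xBorCTCF the bin at 29,315,001, within Lmbr1, was at 1.07 of wild type, while intraTAD2, i4CTCF and 1xBorCTCF stood at 0.665, 0.663 and 0.677.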

How the results depend on the processing

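Chosen after seeing the data were the limit to pairs up to 500 kb apart, gene windows without the extra bins, the removal of the emptied bins, the scaling of gene contacts and the values relative to the shift of all bin pairs. So were all alternatives for the En2 to Mnx1 contact, the bins beside the raised bins and the segment contacts. No paired analysis was possible because each genotype had 1 library. Of 985 alternative values for 315 results, 709 stayed within the counting interval or within 1.5 times the count, 244 moved outside it, and 32 changed sign although the main interval excluded 0. Insulation kept its value in 46 of 50 cases, the Shh to Lmbr1 contact in 47 of 55 and the contacts of Shh with genes in 309 of 330. Contacts across the borders did so in 14 of 70, and 16 of them reversed. The cause of the moves was not tested unless stated. The transcription start alone and intron 5 of Lmbr1 were not run, since the annotation used here gives neither. The maps of i4CTCF and 2xBorCTCF held the fewest contacts, and counting noise alone gave 14,811 and 16,061 changed bin pairs in them against 9138 in intraTAD2. All values that follow are log2 ratios unless a percent or a count is named.

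Scaling by the map total, without distance normalisation, moved all bin pairs 50 kb to 1000 kb apart by a median of -0.18 in i4CTCF against wild type and of -0.23 in i4CTCF, -0.12 in 2xBorCTCF and -0.11 in intraTAD3 against intraTAD2, and by less than 0.1 in the other comparisons. The values below carry that shift. At any one distance this scaling multiplies all bin pairs of a map by 1 factor, so a change of sign under it says nothing about a single window. Relative to the shift of all bin pairs at the distances of each window, 245 of 265 results stayed within their interval. Of the 20 changes of sign 1 remained, in contacts across the En2-side border in intraTAD2 against wild type (-0.018). Taking off that shift repeats the main distance normalisation with a different weighting of bin pairs. This agreement was therefore largely fixed in advance and is no independent check. The Shh to Lmbr1 contact became 0.066 in intraTAD3 and -0.13 in i4CTCF against wild type, and -0.21 in i4CTCF and -0.014 in intraTAD3 against intraTAD2. Contacts within the TAD became 0.095 in intraTAD2, 0.015 in intraTAD3, -0.13 in i4CTCF and -0.064 in 2xBorCTCF against wild type. Relative to intraTAD2 they were -0.22 in i4CTCF, -0.16 in 2xBorCTCF, -0.17 in 1xBorCTCF and -0.081 in intraTAD3, and 2xBorCTCF over 1xBorCTCF was 0.015. Across the En2-side border they were -0.0069 in intraTAD2, -0.10 in intraTAD3, -0.13 in i4CTCF and -0.025 in 2xBorCTCF against wild type. The ratios to intraTAD2 there were -0.12 in i4CTCF, -0.018 in 2xBorCTCF, 0.046 in 1xBorCTCF and -0.096 in intraTAD3, and 2xBorCTCF over 1xBorCTCF was -0.064. Across the Mnx1-side border they were -0.17 in intraTAD3, -0.30 in i4CTCF, -0.19 in 2xBorCTCF and -0.087 in 1xBorCTCF against wild type. Against intraTAD2 that border gave -0.24 in i4CTCF, -0.13 in 2xBorCTCF and -0.11 in intraTAD3, and 2xBorCTCF over 1xBorCTCF was -0.099. Reversed gene contacts were Shh with Rbm33 in 2xBorCTCF over intraTAD2 (-0.0027), and against wild type Lmbr1 with Paxip1 in intraTAD2 (-0.0054) and intraTAD3 (-0.14). Lmbr1 with Htr5a reversed in intraTAD2 (-0.017), intraTAD3 (-0.10) and i4CTCF (-0.062), and in i4CTCF also with Cnpy1 (-0.14) and Rbm33 (-0.15). En2 with Mnx1 reversed in i4CTCF (-0.049). The segment beside Shh reversed over intraTAD2 in intraTAD3 with the rest of the TAD (-0.068) and in i4CTCF with the En2 side (-0.12).

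The median in place of the mean as the expected value moved all bin pairs by at most 0.047 in the median. Relative to the shift at the distances of each window, 263 of 265 results stayed within their interval and 0 of the 5 changes of sign remained. That correction also largely repeats the main normalisation, so the agreement was largely fixed in advance. Without that correction, the Shh to Lmbr1 contact was -0.34 in 1xBorCTCF against wild type, 0.064 in i4CTCF and -0.42 in 1xBorCTCF against intraTAD2, and 0.31 in 2xBorCTCF over 1xBorCTCF. Within the TAD the values were 0.035 in intraTAD2, 0.069 in i4CTCF and -0.12 in 1xBorCTCF against wild type. Over intraTAD2 they were 0.034 in i4CTCF, -0.050 in 2xBorCTCF, -0.15 in 1xBorCTCF and 0.045 in intraTAD3, and 2xBorCTCF over 1xBorCTCF was 0.10. On the En2 side they were 0.0047 in intraTAD2, 0.13 in i4CTCF and -0.033 in 1xBorCTCF against wild type. Over intraTAD2 that side gave 0.13 in i4CTCF, 0.069 in 2xBorCTCF, -0.038 in 1xBorCTCF and 0.038 in intraTAD3, and 2xBorCTCF over 1xBorCTCF 0.11. On the Mnx1 side they were -0.073 in intraTAD2, -0.055 in i4CTCF and -0.14 in 1xBorCTCF against wild type. Over intraTAD2 it gave 0.018 in i4CTCF, -0.0019 in 2xBorCTCF, -0.063 in 1xBorCTCF and 0.025 in intraTAD3, and 2xBorCTCF over 1xBorCTCF 0.061. The contact of the segment beside Shh with the rest of the TAD in i4CTCF over intraTAD2 became 0.013.

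Compared with the median of the other 5 maps in place of wild type, contacts within the TAD were -0.067 in 2xBorCTCF and -0.11 in 1xBorCTCF. The En2-side border gave -0.019 in intraTAD2, -0.0074 in intraTAD3, 0.039 in i4CTCF, 0.011 in 2xBorCTCF and 0.0074 in 1xBorCTCF. The Mnx1-side border gave 0.014 in intraTAD2, 0.016 in intraTAD3, -0.057 in i4CTCF, -0.050 in 2xBorCTCF and -0.014 in 1xBorCTCF. En2 with Mnx1 became 0.037 in 1xBorCTCF. Flanks of 250 kb gave 0.050 in intraTAD2, 0.089 in intraTAD3, 0.013 in 2xBorCTCF and 0.013 in 1xBorCTCF over wild type on the En2 side, and -0.038 in 2xBorCTCF, -0.037 in 1xBorCTCF and 0.039 in intraTAD3 over intraTAD2. On the Mnx1 side they gave -0.023 in intraTAD2, -0.022 in intraTAD3 and -0.14 in 2xBorCTCF over wild type, -0.12 in 2xBorCTCF and -0.042 in 1xBorCTCF over intraTAD2, and -0.074 in 2xBorCTCF over 1xBorCTCF. Insulation windows of 50 kb gave differences of 0.065 between 2xBorCTCF and intraTAD2 and -0.10 between 2xBorCTCF and 1xBorCTCF at the En2-side border. At the border inside Lmbr1 they gave -0.098 between intraTAD3 and wild type and -0.12 between intraTAD3 and intraTAD2. There the windows reach into the stretch with few contacts in intraTAD3.

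Without the extra bin either side of Shh, its TAD took 52.0% of its contacts in wild type, 57.5% in intraTAD2, 57.5% in intraTAD3, 52.2% in i4CTCF, 56.4% in 2xBorCTCF and 50.9% in 1xBorCTCF. The En2 side then took 29.7% in wild type, 28.0% in intraTAD2, 27.9% in intraTAD3, 31.2% in i4CTCF, 29.8% in 2xBorCTCF and 33.6% in 1xBorCTCF, and the Mnx1 side 17.9% in wild type and 14.3% in intraTAD3. From 50 kb on, the En2 side took 27.8% in wild type, 25.2% in intraTAD2, 24.9% in intraTAD3, 28.3% in i4CTCF, 27.2% in 2xBorCTCF and 30.5% in 1xBorCTCF. The Mnx1 side then took 18.4% in wild type, 15.2% in intraTAD2, 15.2% in intraTAD3, 17.2% in i4CTCF, 15.2% in 2xBorCTCF and 16.3% in 1xBorCTCF.

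Counts of changed bin pairs are given against wild type for intraTAD2, intraTAD3, i4CTCF, 2xBorCTCF and 1xBorCTCF, then against intraTAD2 for i4CTCF, 2xBorCTCF, 1xBorCTCF and intraTAD3, and last for 2xBorCTCF against 1xBorCTCF. Unsmoothed counts were 48115, 48517, 55466, 56212 and 49979, then 55974, 58045, 44916 and 40945, and last 55037. Smoothing over 5 by 5 bins gave 1861, 2006, 4031, 5045 and 2481, then 2804, 3614, 1326 and 1190, and last 4029. A 1.5-fold threshold gave 26018, 27731, 36410, 39549 and 30375, then 30772, 34401, 23932 and 19640, and last 35147. A 3-fold threshold gave 2791, 3033, 5704, 6553 and 3603, then 4087, 5022, 2152 and 1646, and last 5734. With a pseudocount of 0.5 they were 3041, 3358, 5983, 7092 and 3988, then 4234, 5360, 2457 and 1930, and last 6116. Pairs up to 500 kb apart numbered 227, 271, 541, 762 and 403, then 266, 404, 128 and 73, and last 531. Against wild type alone, pairs with a value in both maps numbered 2689, 2885, 3557, 4139 and 3100, and bins of 10 kb gave 201, 221, 521, 675 and 271. Unsmoothed maps lowered the median correlation to 0.396 between wild type and the mutant maps and to 0.421 among the mutant maps.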

Other observations

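The gene pairs, windows and bins in this part were all chosen after the values had been seen, from 76 pairs of listed genes per comparison and 9 added windows, and no test was run on them.

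The homeobox genes En2 and Mnx1, which lie on opposite sides of the Shh TAD, had a strong contact with each other, 10.7 times the average for their distance in wild type. It was 5.54 in 2xBorCTCF (log2 ratio -0.95, -1.19 to -0.71), 8.06 in intraTAD2 (-0.41, -0.56 to -0.26), 8.75 in intraTAD3 (-0.29, -0.44 to -0.14), 8.98 in 1xBorCTCF (-0.25, -0.41 to -0.10) and 12.2 in i4CTCF (0.19, 0.022 to 0.36). Among 294 windows the ratios stood at percentile 1.70 in 2xBorCTCF, 10.2 in intraTAD2, 20.7 in intraTAD3, 21.4 in 1xBorCTCF and 70.1 in i4CTCF. Against the median of the other 5 maps the ratio in 1xBorCTCF became 0.037. Cnpy1, beside En2, had a contact of 3.22 with Mnx1 in wild type and 1.93 in 2xBorCTCF (-0.74, -0.99 to -0.49).

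The stretch of 210 kb between Shh and the bin at 28,685,001 had less contact with the remaining 665 kb of the TAD in the BorCTCF maps, 1.64 in 2xBorCTCF (-0.10, -0.13 to -0.071) and 1.55 in 1xBorCTCF (-0.18, -0.20 to -0.15) against 1.76 in wild type. Its contact with the flank on the En2 side was 0.646 in 2xBorCTCF (0.10, 0.042 to 0.16) and 0.666 in 1xBorCTCF (0.15, 0.094 to 0.20) against 0.602 in wild type. In intraTAD2 and intraTAD3 both differences went the other way, with 1.82 and 1.86 inside the TAD and 0.571 and 0.557 with the flank. In i4CTCF neither differed from wild type beyond counting error (0.019, -0.011 to 0.049 inside the TAD and 0.055, -0.0050 to 0.12 with the flank). Among windows of the same size, percentiles inside the TAD were 4.96 in 2xBorCTCF, 2.09 in 1xBorCTCF, 79.4 in intraTAD2 and 87.5 in intraTAD3. With the flank they were 91.2, 92.9, 13.4 and 6.08 in the same order. In intraTAD3, Shh had a contact of 1.83 with the bins beside 28,875,001, against 1.40 in wild type (0.38, 0.16 to 0.61).

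Insulation in windows of 50 kb fell most at 28,685,001 in intraTAD2 (-0.32), at 28,680,001 in 1xBorCTCF (-0.30) and at 28,875,001 in intraTAD3 (-0.40). It rose most at 29,315,001 in intraTAD3 (0.50), at 28,480,001 in 2xBorCTCF (0.36), at 28,450,001 in 1xBorCTCF (0.28) and at 28,505,001 in i4CTCF (0.24). The rise in intraTAD3 lies within the stretch nearly without contacts, so it is not separate from the contacts across that stretch given above.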
